A study of Mus musculus with 4 samples.

How the data were processed

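Small RNA below 200 nt was isolated from the brains of mice aged 2 months, wild type or homozygous for a knock-in mutation of Wdr4, per the labels' protocols. Each genotype gave 1 library treated with the demethylase AlkB, and 1 library treated with AlkB and then with NaBH4 and aniline, which reduce RNA and cut it at 7-methylguanosine (m7G). The 4 libraries form 4 groups of 1, so no test between genotypes was run and no p-value is given.

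The authors deposited a cleavage table for each genotype and a table of tRNA read counts. Bowtie2 and the mouse build mm10 are named in the submitters' processing notes; the version, the counting tool, the filters and the handling of reads that fit several tRNAs are not given in the sources used here. Each cleavage table holds, per the file headers and values, the count of reads starting at a tRNA position and the count of reads covering it, for an uncleaved and a cleaved library. The library codes in the tables end in D and R, which were taken as the uncleaved and the cleaved library. The log2 cleavage score deposited by the authors is the share of covering reads that start at the position in the cleaved library, divided by the same share in the uncleaved library. Scores were recomputed from the counts and equalled the deposited ones. The wild type table holds 155 rows for 116 tRNA genes and lists no score below 4.02. The mutant table holds 8397 rows for 418 genes and lists positive scores down to nearly 0. The tables can therefore be compared as lists only above a score of 4. Every listed position has at least 1 uncleaved read start, so positions without one are missing from both, and a filter on depth is not excluded.

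Cleavage leaves a read that starts 1 nucleotide after the modified base, so the base named is the one before the read start, counted from 1 at the 5′ end of the mature sequence as the tables number it. Gene copies with identical sequences carry identical counts and were collapsed to 1. The site was defined before the data were examined as the fourth base of the motif RAGGT (R is A or G) lying at nucleotides 40 to 52, which 84 of 228 sequences hold. The planned threshold for a cleaved site was a score of 1. The planned comparison of score differences with random positions could not be made, because the wild type table lists few other positions; the mutant scores at all listed motif sites were instead compared with 10000 random draws of other listed positions of the same tRNAs. A second class, a G after another G at nucleotides 45 to 47 outside the motif, was added after the data were seen. Shares have 95% Wilson intervals. The interval of a median score difference comes from 2000 binomial redraws of the read starts. Intervals cover counting error only, since the reads carry no molecular identifiers. Intervals of medians redraw sequences that share reads as if they were separate, so they can be too narrow. Median covering reads per listed position were 14689 (uncleaved) and 30398 (cleaved) in wild type, and 3965 and 3526 in the mutant. These medians are over different sets of positions, so they do not compare the depth of the libraries. At positions listed in wild type, uncleaved covering reads were lower in the mutant for 11 of 28 anticodons.

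In the abundance table the authors deposited whole-number read counts for 272 mature tRNA names, 464 tRNA locus names and 68191 names starting with tRX; near-identical tRNAs carry nearly the same reads, as 1 read is counted for several names. Its columns name the genotype and not the library, so they are given as the authors' values and a column total is not a library depth. Mature names were summed by anticodon and scaled to the mature tRNA total, with a pseudocount of 0.5 and at least 100 reads over both columns, and 1.5-fold was taken as a difference of size. The lists were fixed before the data were examined: list 1, 25 anticodons reported to carry m7G; list 2, the Leu, Ser and SeC tRNAs, which have a long variable arm; list 3, the other nuclear anticodons. List medians were compared with 10000 random lists matched on read count in 5 strata. In an alternative added after the data were seen, anticodons of 1 amino acid whose most abundant isodecoders had counts within 5% in both columns were merged. Mitochondrial tRNAs and microRNA markers were not used here. The text names the 10 sites with the highest wild type score and the 10 with the largest fall, the 8 anticodons with the largest rise and the 8 with the largest fall in abundance, and a set fixed in advance that includes the Lys, Val, Met, Phe, Trp, Cys and Arg-TCT tRNAs.

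Tables were processed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9. The calculations were tested on simulated data: a planted score difference was recovered in 100 of 100 runs over 89 positions, and a planted shift in abundance was placed below the random lists in 19 of 20 runs over 50 items, while 18 of 20 lists without a shift stayed within the 95% range. The simulated scores had the wild type depths in both genotypes, the same uncleaved share at every position and no shared reads. They thus did not test uncleaved shares as low as those seen, or shared reads. Alternatives covered the site definition, gene copies, thresholds, scaling, minimum reads, pseudocount and level of summing.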

Results

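Cleavage sequencing of brain tRNA was done on 1 wild type and 1 homozygous Wdr4 mutant sample set, each with an uncleaved and a cleaved library. Wdr4 (chromosome 17, 31494322 to 31519985, mm10) encodes the partner of Mettl1 (chromosome 10, 127041549 to 127046365) in the enzyme that places m7G in the variable loop of tRNAs. The comparison asks which tRNAs carry the modification in mouse brain and how this differs in the mutant. Reads covering a listed position ranged from 56 to 335721 in the wild type uncleaved library and from 153 to 1968190 in the cleaved one. The mutant ranges were 2 to 2649150 and 1 to 1826520. Wdr4 mRNA itself was not measured in these small RNA libraries. With 1 library per group, no difference below has a replicate check.

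Cleavage at the predicted m7G site was lower in the mutant than in wild type for all 33 tRNA sequences listed in both tables. The median share of covering reads starting just after the site in the cleaved library was 28.2% in wild type and 1.89% in the mutant. The median cleavage score was 5.83 in wild type and 2.34 in the mutant, and the median difference was -4.02 on the log2 scale (95% counting interval -4.11 to -3.72). These sequences cover 13 anticodons and rest on 20 distinct sets of cleaved reads, because near-identical tRNAs share reads. With sequences sharing cleaved reads collapsed to 20, a setting added after the data were seen, the median difference was -4.07 (-4.36 to -3.77). A further 3 sequences, of Arg-TCT and Phe-GAA, were listed in wild type and not in the mutant table.

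The largest difference was in a Phe-GAA tRNA (gene chr13.trna480, base 46), where the score was lower by a difference of -5.99 on the log2 scale. Its cleaved share was 6.82% (Wilson interval 6.56 to 7.10) in wild type and 0.125% (0.0808 to 0.193) in the mutant. The more deeply covered Phe-GAA gene chr10.trna427 had 13.3% and 0.348%. Arg-TCT of chr1.trna313 had 8.27% in wild type and 0.130% in the mutant, and Arg-TCT of chr19.trna250 had 15.9% and 0.397%. Ala-AGC of chr13.trna36 had scores of 6.76 and 2.08. Trp-CCA of chr11.trna832 had 45.6% and 1.33% (1.20 to 1.48). Met-CAT of chr13.trna485 had 28.2% and 1.64%. Cys-GCA of chr11.trna345 had scores of 6.93 and 2.80, and Cys-GCA of chr6.trna457 had 6.80 and 2.73. Val-CAC of chr13.trna61 had scores of 6.52 and 1.27, and Val-AAC of chr13.trna459, which shares its reads, had 6.50 and 1.27. Trp-CCA of chr11.trna190 had scores of 6.35 and 2.34, and Arg-TCT of chr13.trna478 had 5.59 and 0.97.

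The share of wild type cleavage that remained in the mutant, after subtracting the uncleaved library, differed between tRNAs. It was lowest in Arg-TCT of chr19.trna250, at 0.544%, and had a median of 4.52% over the 33 sequences. In Trp-CCA the median over 5 sequences was 2.60%, and 4 of the 5 share 1 set of 20133 wild type and 334 mutant cleaved reads. Higher values were found in Cys-GCA (median 21.2% of 4 sequences), Val-AAC (22.2% of 5) and Val-CAC (22.5% of 3). The Val values near 22% all come from 1 shared set of 3016 wild type and 156 mutant cleaved reads, which also gave 22.8% in a Gly-ACC tRNA. The Val sequences with other reads had 10.2% (chr13.trna459), 10.1% (chr13.trna61) and 12.9% (chr13.trna59). A Met-CAT tRNA (chr13.trna46) was the only motif site with a mutant score above 4, at 4.35, with 18.2% of its mutant reads cleaved (10.7 to 29.1). That score rests on 12 of 66 covering reads in the mutant cleaved library and 1 read start in the uncleaved one.

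The Lys-TTT, Thr-TGT, Tyr-GTA, Ala-TGC and Ala-CGC sequences listed in wild type at nucleotides 45 to 47, with 1 of Arg-CCT (chr6.trna49) and 1 of Trp-CCA (chr10.trna384), lack the strict motif there and were cleaved at a G following another G, a class added after the values were seen. Lys-TTT (chr1.trna197, base 46) had 42.0% in wild type and 2.68% in the mutant. Thr-TGT of chr11.trna92 had 26.9% and 2.07%. The 16 such sequences listed in both tables all had lower scores in the mutant, with a median difference of -3.93.

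**Figure D1:**
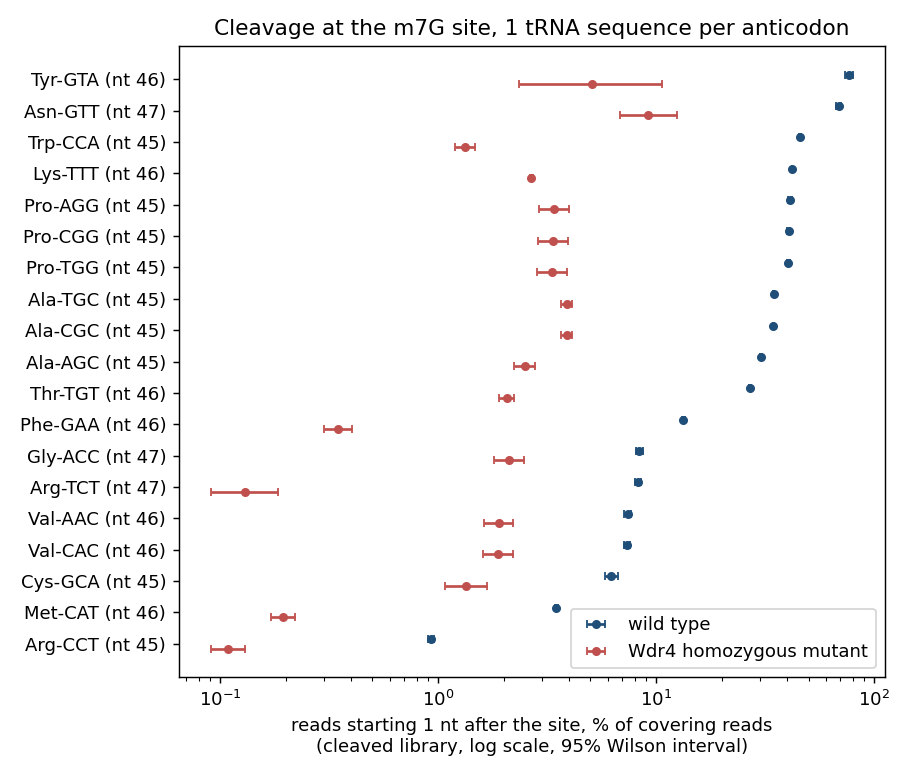
Share of covering reads that start just after the m7G site in the cleaved library (percent, log axis), for the most deeply covered tRNA sequence of each of 19 anticodons, in wild type (blue) and mutant (red). Bars are 95% Wilson intervals; Lys-TTT lies at 42.0% in wild type and 2.68% in the mutant.

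Above a score of 4, the range that both tables list, 36 motif sites stood in the wild type table and 1 in the mutant table. At the planned threshold of 1 the counts were 36 and 29, where the wild type count is a lower limit because its table lists no score below 4.02. Over the 49 motif sites of the mutant table whose tRNAs had other listed positions, the median mutant score was 1.27, against 0.83 for random draws of those positions (95% range 0.53 to 1.18). The median was 2.34 in the 33 sites also listed in wild type, which were selected there for high cleavage, and 0.55 in the 17 listed in the mutant alone. Of the 84 sequences with the motif, 48 were not listed in wild type. Of these 48, 17 were listed in the mutant table, Val-TAC, Ile-AAT and Asn-GTT tRNAs among them. In these 17 a median of 16.8% of mutant reads already started at the site without cleavage. In Val-TAC of chr19.trna49 the mutant share was 36.8% in the uncleaved and 40.6% in the cleaved library. The main Lys-CTT tRNA (chr11.trna895, base 46) had 5.26% and 7.11% in the mutant and was not listed in wild type. Another Lys-CTT sequence (chr3.trna3) was listed in wild type at base 40, with 52.4% cleaved and a score of 5.35, and not in the mutant. It lacks the strict motif and is counted below among the other positions.

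Outside the m7G site, Glu-TTC and Arg-CCG tRNAs had nearly the same cleavage in both genotypes; both were picked after their values were seen. Glu-TTC of chr1.trna680 had 4.36% of reads cut at base 43 in wild type and 3.97% in the mutant, and Arg-CCG of chr17.trna431 had 1.71% in both at base 42. Over all 34 other positions listed in both tables, many of them within a few nucleotides of a site, the median difference was -1.40 (counting interval -2.04 to -0.86), and 31 of them were lower in the mutant. In sequences with no listed site it was -1.30, with 14 positions lower and 2 higher. At the 6 positions with at least 10 uncleaved read starts in both genotypes, 4 of them in Glu-TTC, it was -0.32. Above a score of 4, other positions numbered 36 in wild type and 25 in the mutant, and 6 were above 4 in both. At least 10 read starts in both libraries of the genotype were held by 6 of the wild type and 7 of the mutant positions. Class II tRNAs, which have a long variable arm, had 3 wild type positions above 4 (Leu-AAG, Ser-TGA and SeC-TCA), none of them at nucleotides 40 to 52. The mutant table had 1, in SeC-TCA at base 48, with 1 read start in the uncleaved library.

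**Figure D2:**
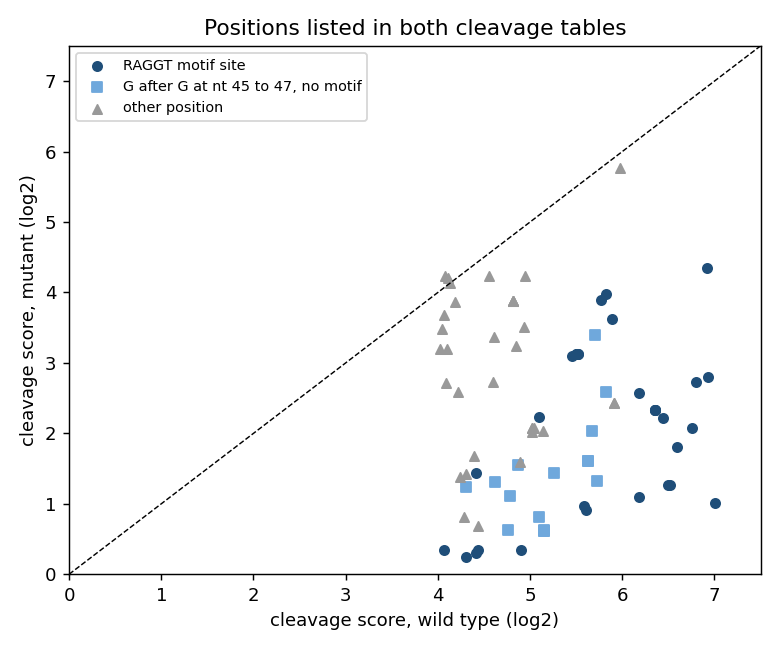
Log2 cleavage score in wild type (x) against mutant (y) for each position listed in both tables; the dashed line marks equal scores. All 33 motif sites (dark circles) and 16 other G sites (squares) lie below the line, while 3 of the 34 remaining positions (triangles) lie above it.

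Anticodons reported to carry m7G were lower as a group in the mutant column of the authors' abundance table, with Ala-TGC and Ala-CGC lowest. Their log2 ratios of mutant to wild type were -1.41 and -1.13. Val-AAC had -0.80, Val-CAC -0.79, Pro-TGG -0.81, Pro-CGG -0.76, Thr-TGT -0.75, Lys-CTT -0.69 and iMet-CAT -0.60. Gly-ACC, outside the reported list, had -0.94 and shares cleaved reads with Val tRNAs. Arg-TCT (0.57), Met-CAT (0.51) and Trp-CCA (0.36) were the highest, although their cleavage was lower too, and none reached 1.5-fold.

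Of 50 anticodons, 13 were at least 1.5-fold lower and 0 at least 1.5-fold higher, and 12 of the 13 were in list 1. The scaling total rests mostly on Gly-GCC and Gly-CCC, whose names count many of the same reads. They held 63.4% of mature reads in the wild type column and 67.4% in the mutant column. Scaled by the median ratio over anticodons, 9 were lower and 2 higher. The list 1 median was -0.54 over 25 anticodons, below all 10000 matched random lists (95% range -0.26 to -0.08). These draws treat anticodons as separate items, although some count nearly the same reads. They are the Pro anticodons, Val-AAC and Val-CAC, Ala-TGC and Ala-CGC, Arg-CCG and Arg-TCG, and Gly-CCC and Gly-GCC. With such anticodons merged to 44 items, the list 1 median was -0.34 over 20 items, below all but 0.08% of random lists (95% range -0.24 to -0.02). Of the 44 items, 9 were at least 1.5-fold lower, 8 of them in list 1. The merging moved Gly-CCC, a list 1 anticodon with a ratio of 0.09, out of list 1 with Gly-GCC. Keeping it in list 1 would raise the median to the value of Val-TAC, -0.23, which lies inside the 95% range above. The placement of the merged list below the random lists thus depends on this move. Random lists were not drawn for that setting. The median was -0.11 for the 11 Leu, Ser and SeC anticodons and 0.02 for the 14 others; the median of all anticodons was -0.15. The next highest ratios were in Gln-TTG (0.21), Leu-CAA (0.19), SeC-TCA (0.14), Arg-CCG (0.13) and Cys-GCA (0.13). Lys-TTT had -0.12, Phe-GAA -0.18 and Val-TAC -0.23. The brain-enriched Arg-TCT isodecoder tRNA-Arg-TCT-4 had 21136 reads in the wild type column and 44725 in the mutant column, a scaled log2 ratio of 0.56, and the locus tRNA-Arg-TCT-4-1 had 53 and 111 (0.46, scaled to the locus total). At isodecoder level the list 1 median was -0.25. The columns do not name their library.

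**Figure D3:**
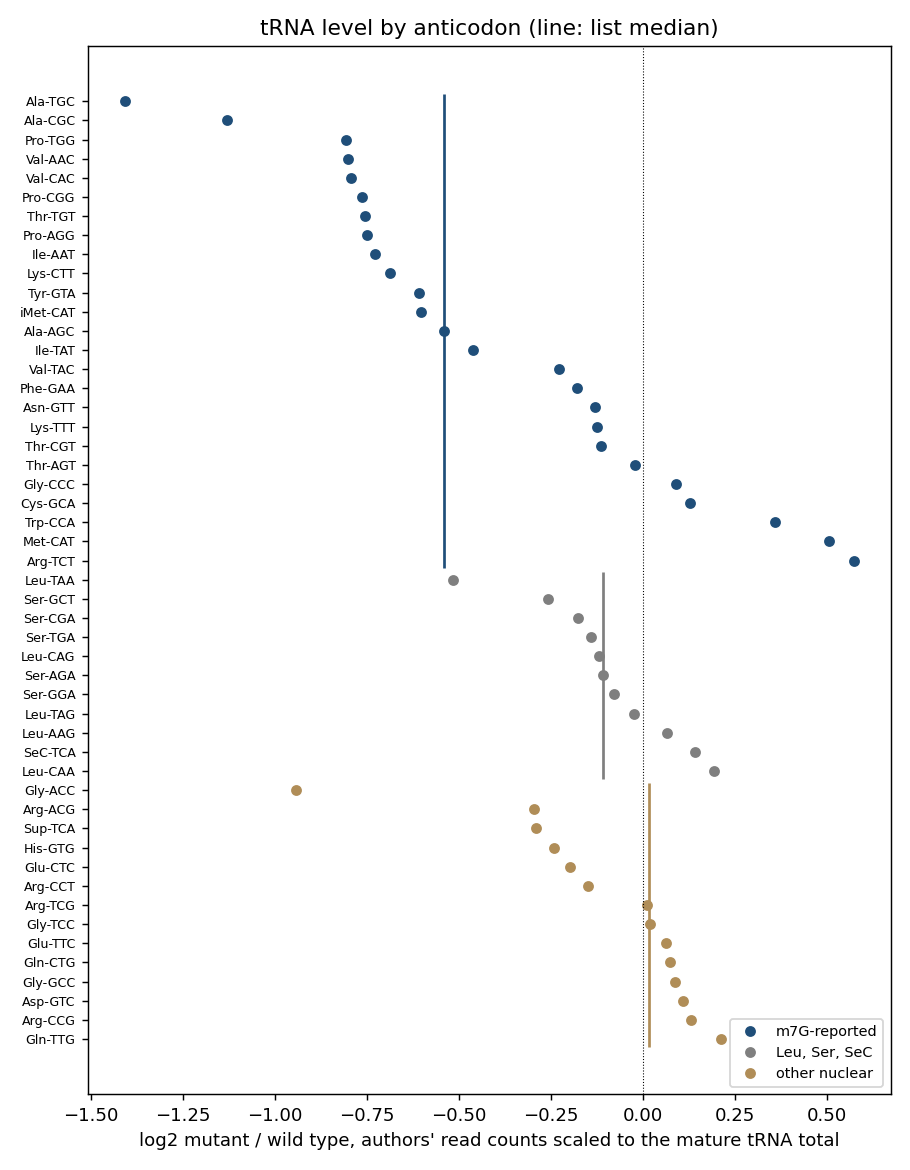
Log2 ratio of the authors' read counts, mutant over wild type, for each of 50 anticodons scaled to the mature tRNA total; vertical lines are list medians. The m7G-reported list has its median at -0.54, against -0.11 for Leu, Ser and SeC and 0.02 for other nuclear tRNAs.

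Between the uncleaved and the cleaved library of the same genotype, Lys-TTT covering reads were 335721 and 1968190 in wild type and 453911 and 366909 in the mutant. The unscaled log2 ratio of cleaved to uncleaved covering reads had a median of 1.29 in wild type and -0.25 in the mutant over 18 list 1 anticodons. It was 1.33 and -0.43 over 10 other anticodons, so a loss of list 1 reads on cleavage was not detectable. Library totals are not used here, and the covering reads include the cleaved fragments.

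The tRNAs with the larger loss of cleavage were not clearly those with the larger loss of abundance. Across 13 anticodons, which are not independent replicates, Pearson's r between score difference and abundance ratio was -0.284 and Spearman's rho was -0.423. All score differences are below 0, so this sign means that a larger loss of cleavage went with a higher mutant abundance. The 2 anticodons farthest from the median score difference were Gly-ACC and Val-AAC. Without them r was -0.0436 and rho -0.0909, so the relation rests on those anticodons. Gly-ACC shares its cleaved reads with most listed Val sequences, and the Pro anticodons share another set. The 13 anticodons are therefore fewer separate measurements. The relation was 1 of 6 computed.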

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

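The tests of explanations in this part were chosen after the results were seen; the abundance gap in anticodon sums and over all isodecoders was planned. Rows of the abundance table outside the mature tRNA names held reads outside the comparisons of tRNA level by anticodon. Names starting with tRX held 227178 reads in the wild type column and 298451 in the mutant column, and tRNA locus names held 217910 and 329697. The tRX names with most reads were tRX-Lys-NNN-22 (121515 and 153702), tRX-Gly-NNN-5 (41248 and 61257) and tRX-His-NNN-2 (27848 and 41250).

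Lower cleavage at the motif sites of the mutant had 3 technical explanations. The tables argue against selection and few reads as the whole cause, and do not settle a weaker reaction. A weaker reaction on mutant RNA would lower other positions that it cuts alike. The median difference at other positions was -1.40 (counting interval -2.04 to -0.86) against -4.02 at the sites. It was not shown that the reaction cuts these positions. Of the 36 listed in wild type, 6 had at least 10 read starts in both wild type libraries, so the contrast cannot decide. Selection of high wild type scores would leave many mutant sites above 4, and 1 was found; few reads would end the difference at deep sites, and it was -4.02 at the 28 with at least 1000 covering reads in all 4 libraries. A part of the fall may still come from selection, and the share due to the reaction stays open. The genotype remains a candidate explanation that 1 library per group cannot separate from differences between animals or preparations.

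The lower abundance of m7G-reported anticodons was weighed against counting and library effects. In the covering reads of the uncleaved libraries, which are named, the list 1 median lay -0.70 from that of the other anticodons. It lay -0.13 from it with anticodons that count the same reads merged (14 list 1 items), so these reads do not settle the gap. They come only from positions listed in wild type, which can belong to minor sequences. The table's ratios lay nearest to the uncleaved pairing in 22 of 28 anticodons (median gap 0.19). They lay nearest to wild type uncleaved with mutant cleaved reads in 6 (median gap 0.52). These values argue against columns of different library kinds for most of those anticodons but do not exclude them. Shared reads stay open as a cause. In the table the gap was -0.46 both in the anticodon sums and with 1 isodecoder per anticodon. It was -0.25 with anticodons that count the same reads merged, which puts Gly-CCC outside list 1, and -0.19 over all isodecoders. Genotype and differences between single animals are untested.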

How the results depend on the processing

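Several alternatives, named here as added, were chosen after seeing the data. The site score difference of -4.02 kept its sign under all 10 alternatives; it was -3.66 at the highest wild type score within the window, -2.07 at the highest mutant score (16 sequences listed in both), -3.40 at the highest mean score and -3.69 as a mean over tRNAs. The number of cleaved sites depends on the threshold. In the mutant it was 29 at a score of 1, 11 at 3, and 1 above 4 (added; also 1 with the added G class). Taking the highest wild type score gave 61 in wild type and 44 in the mutant, and counting every gene copy 63 and 48.

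Some abundance alternatives used covering reads of the cleaved libraries. These include the cleaved fragments, so they do not measure abundance alone. Merging anticodons in the table puts Gly-CCC outside list 1. The list 1 abundance median of -0.54 stayed negative under all 14 alternatives. It was -0.40 scaled by the median ratio, -0.60 scaled to anticodons with no reported m7G, -0.25 at isodecoder level, -0.89 in covering reads of the cleaved libraries, -0.70 in those of the uncleaved libraries (added), -0.34 with anticodons that count the same reads merged (added), -0.87 and -0.13 with such merging in covering reads of the cleaved and uncleaved libraries (added) and -0.57 without Gly-CCC (added). The gap to the other anticodons, -0.46, was -0.42 with no minimum of reads, -0.52 with 1000 reads, -0.45 with a pseudocount of 5, -0.19 at isodecoder level, -0.25 with anticodons merged, -0.89 and -0.70 in covering reads of the cleaved and uncleaved libraries (-0.87 and -0.13 merged), and -0.49 without Gly-CCC. Anticodons at least 1.5-fold lower numbered 13. The count was 9 under median-ratio scaling, and 14 scaled to anticodons with no reported m7G or with no minimum of reads. It was 11 in uncleaved covering reads. With merging it was 9 in the table, 9 in cleaved and 7 in uncleaved covering reads. Those at least 1.5-fold higher numbered 0, but 2 under median-ratio scaling, 3 in covering reads of the uncleaved libraries, merged or not, and 1 with the most abundant isodecoder (added); at isodecoder level 6 isodecoders were higher and 44 lower, more items being counted. The cause of the other shifts was not tested.

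The correlation of abundance with cleavage, rho -0.423, was 0.0396 at isodecoder level, where covering reads of the uncleaved libraries also replaced the table's counts, and -0.0909 without the 2 farthest anticodons. No paired analysis was possible because each group has 1 library and no test was run; leaving out a replicate was not possible either. Low depth limits sites with few read starts in the uncleaved libraries.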

Other observations

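The test in this part was chosen after the result was seen. Among tRNA locus names with at least 100 reads over both columns, some loci of Val-CAC, Ala-CGC, Ile-TAT and Pro-AGG stood higher in the mutant column, while the mature names of these anticodons were lower. tRNA-Val-CAC-2-4 had 49 reads in the wild type column and 396 in the mutant column, a log2 ratio of 2.40 scaled to the locus total (counting interval 1.98 to 2.83). tRNA-Ala-CGC-2-1 had 29 and 188, tRNA-Ile-TAT-2-3 had 46 and 284, and tRNA-Pro-AGG-1-1 had 64 and 343. Other loci of Pro-AGG and Val-CAC went the other way, as tRNA-Pro-AGG-1-5 (1006 and 1188, log2 ratio -0.36) and tRNA-Val-CAC-2-3 (51 and 61, -0.34). Summed over loci, the ratio was 1.63 for Ile-TAT, 0.99 for Val-CAC, 0.74 for Ala-CGC and -0.16 for Pro-AGG. Of 188 such loci, 16 were at least 2-fold higher and 5 at least 2-fold lower. All 16 of the higher and 4 of the 5 lower loci were among the 88 loci of list 1, whose median over anticodons was -0.15, within the range of random lists (-0.21 to 0.02). The locus names thus gave no lower list 1, and the median was -0.22 for list 3. The lowest were tRNA-Lys-TTT-5-1 (153 and 59) and tRNA-Ala-TGC-2-1 (130 and 72). These loci were picked by size after their values were seen.

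The abundance table may have been counted from the uncleaved libraries. Over 28 anticodons, the unscaled log2 ratio of mutant to wild type in the table lay a median of 0.19 from that in the uncleaved covering reads and 1.87 from that in the cleaved ones. The cleaved ratio was below 0 in all 28, while the table's was above 0 in 16. The gap was 0.52 for wild type uncleaved with mutant cleaved reads, 1.48 for the reverse pairing and 1.14 for the sum of both libraries. Uncleaved reads were the nearest of these 5 in 22 anticodons and wild type uncleaved with mutant cleaved in 6. By level rather than ratio, 13 of the 28 lay nearer the uncleaved than the cleaved reads in both genotypes. Covering reads come only from positions listed in wild type, which can belong to a minor sequence, so levels need not match. Asn-GTT had 310 uncleaved wild type covering reads against 28607 reads in the wild type column, while Thr-TGT had 55234 against 55836.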
